A study of Caenorhabditis elegans with 9 samples.

How the data were processed

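Total RNA of mixed-stage C. elegans embryos was hybridised, as biotin-labelled cRNA, to 9 Affymetrix C. elegans arrays, 3 for each of control, sdc-2(y93)+RNAi and smo-1 RNAi embryos. The deposited values are on the log2 scale and were made by RMA in Affymetrix Expression Console, per the submitters' processing notes, which give no version. RMA corrects background, normalizes probes by quantiles and summarises each probe set by median polish; its options, and whether the 9 arrays were processed together, are not given in the sources used here. RMA makes the arrays' distributions alike, so a change of all transcripts together cannot be seen, and differences of dim genes are compressed. Array medians over probe sets lay between 6.51 and 6.72.

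Groups and replicate numbers came from the sample titles. Of 22625 probe sets, 77 are manufacturer controls, 887 were listed with several genes and 895 were not listed in the platform annotation used here. The other 20766 have 1 gene each, and the gene identifiers of 20701 of these were found in the RefSeq gene table of assembly WBcel235, which gave current symbols and chromosomes; no coordinates of it are printed. Each of the 17118 genes was represented by its probe set with the highest mean over all 9 arrays. For 4237 genes this probe set is of a kind that can bind related transcripts, which the text marks for some named genes only. X-linked genes numbered 2353 and autosomal genes 14718.

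Genes were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on all 9 arrays with 6 residual degrees of freedom and no covariate. The tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Each perturbed group was compared with control, and smo-1 RNAi with sdc-2(y93)+RNAi. Errors of fold changes are standard errors of that fit. The X shift is the median log2 fold change of X-linked genes minus that of autosomal genes, over the 1380 and 7152 genes whose mean level was above the median of 6.65. It was tested with camera, at a preset correlation of 0.01 and at an estimated one, and by exact permutation of the shifts of single arrays. A total of 23 gene lists, fixed before the data were examined, were tested with camera in the same way, adjusted over the lists of each comparison. Members that could not be matched by symbol, or that were read only by probe sets shared between genes, were not measured. The covariance that shared control arrays give without effects was simulated in 100 draws, and the overlap was also counted with the control arrays divided between the comparisons.

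Genes named in the text followed a rule fixed before the data were examined. For each comparison with control it took smo-1, sdc-2 and her-1, and the 8 highest and 8 lowest genes past the threshold whose arrays did not overlap those of control. It also took the 4 X-linked genes with the smallest adjusted p, and up to 3 members of each list with the smallest adjusted p past the threshold, or up to 2 given as values where none passed. For the direct comparison it took the 6 highest and the 6 lowest. The text prints most, not all, of them.

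The steps were tested on simulated data over 17118 genes with 200 changed, with normal noise of each gene's residual spread. At a log2 change of 1, 100% of the changed genes were recovered in the simulated smo-1 RNAi comparison and 98.5% in the simulated sdc-2(y93)+RNAi comparison; at 0.5 the shares were 56.1% and 53.0%. Of 16918 unchanged genes, 14 and 6 were called. An X shift made at 0.4 was recovered as 0.39 and 0.40.

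Alternatives for the probe sets were the mean of all probe sets of a gene, no probe sets of the kinds that can bind related transcripts, and only genes above the median level. Alternatives for the fit were eBayes with trend and robust settings, array weights, the replicate number as a block, only the 6 arrays compared, and leaving out each array. Alternatives for the scaling were centring each array on autosomal genes and another quantile normalization. Stricter thresholds were an adjusted p of 0.01 and a minimum fold of 1.5, and the X shift was also computed with other summaries and gene sets. Centring on autosomal genes above the median level, and lists with members and background placed on autosomes alone, were added after seeing the data. No array was left out of the main results.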

Results

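Transcript levels were measured in mixed-stage embryos of XX hermaphrodites of the nematode Caenorhabditis elegans on 9 Affymetrix arrays, 3 per group. Control embryos came from wild-type (N2) mothers fed bacteria carrying the empty RNAi vector L4440. The smo-1 RNAi embryos came from mothers fed bacteria making double-stranded RNA against smo-1, the gene of the small ubiquitin-like modifier SUMO. The third group carried the sdc-2 allele y93 and received RNAi as well, and is called sdc-2(y93)+RNAi here. SDC-2 is the protein that brings the dosage compensation complex, a condensin-containing assembly that lowers expression from both X chromosomes of hermaphrodites, to X. Control mothers spent 96 hours on RNAi plates, and mothers of the other groups 24 hours on HB101 bacteria and then 72 hours on RNAi plates, all at 20 °C. The number of arrays limits the precision of every value. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

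The smo-1 messenger was 12.7-fold lower in smo-1 RNAi embryos than in control embryos. Its log2 level was 11.93 ± 0.13 (SD, n = 3) in control, 8.26 ± 0.38 (n = 3) in smo-1 RNAi and 10.88 ± 0.12 (n = 3) in sdc-2(y93)+RNAi embryos. The fall of the smo-1 messenger in smo-1 RNAi embryos was -3.67 ± 0.17 (log2, SE, limma adjusted p = 6.5e-08). In sdc-2(y93)+RNAi embryos smo-1 was also lower, by 2.07-fold (log2 -1.05 ± 0.17, limma adjusted p = 0.00094). The sdc-2 messenger was read by a pair of probe sets that differed. The brighter one gave -0.35 ± 0.16 in sdc-2(y93)+RNAi embryos (limma adjusted p = 0.14), and the other, marked by the manufacturer as matching several transcripts, gave -1.38 ± 0.10 (limma adjusted p = 1.2e-05 over all probe sets). In smo-1 RNAi embryos the same probe sets of sdc-2 gave -0.12 ± 0.16 and -0.67 ± 0.10. The positions of the probes and of the lesion are not given in the sources used here, and y93 need not lower the messenger, so the sdc-2 level does not check the labels by itself. The gene her-1, which promotes male development and is repressed by SDC-2 in hermaphrodites, was 5.57-fold higher in sdc-2(y93)+RNAi embryos (log2 2.48 ± 0.10, limma adjusted p = 4.2e-07). In smo-1 RNAi embryos her-1 differed from control by 0.32 ± 0.10 (limma adjusted p = 0.032), a call lost when any of 4 arrays was left out.

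**Figure D1:**
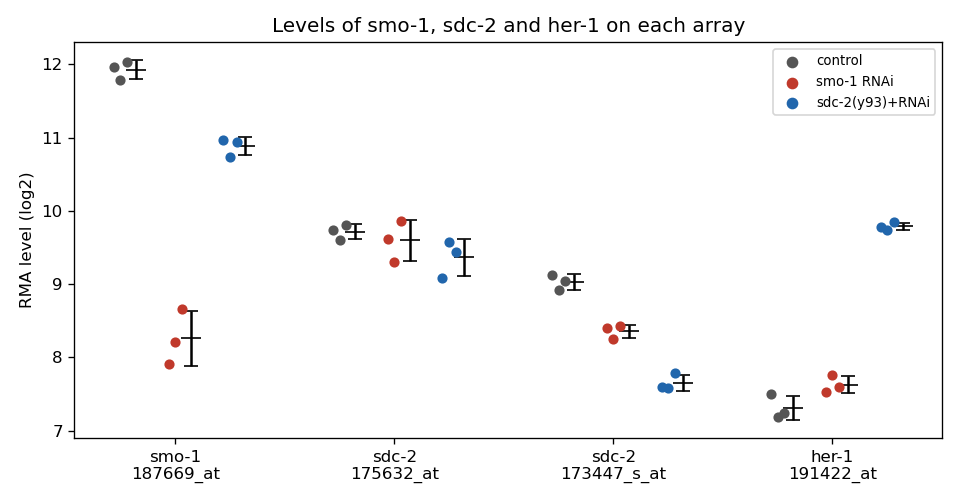
Log2 RMA levels of smo-1, of both sdc-2 probe sets and of her-1 on each of the 9 arrays (points), with the mean and SD of each group of 3 beside them. The smo-1 level lies at 8.26 on average in smo-1 RNAi embryos against 11.93 in control embryos, and her-1 is higher in sdc-2(y93)+RNAi embryos by 2.48.

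The first comparison asked whether loss of SUMO changes expression from the X chromosome. In smo-1 RNAi embryos X-linked genes above the median level were higher relative to autosomal genes by 0.46 on the log2 scale, a 1.38-fold difference, and over genes of any level by 0.16. Among genes above the median level, the median log2 fold change against control was 0.23 for 1380 X-linked genes and -0.24 for 7152 autosomal genes, and 77.7% of the X-linked genes lay above the autosomal median. Of 2353 X-linked genes tested, 34.8% rose and 12.2% fell, against 15.0% and 23.8% of 14718 autosomal genes (Fisher's exact test for the higher genes, odds ratio 3.01, p = 2.8e-103, a description of where the calls lie, since genes are not independent replicates). The X-linked genes with the smallest adjusted p were C45B2.2 (log2 6.22 ± 0.11), F53A9.6 (4.69 ± 0.11), F53A9.8 (5.14 ± 0.12) and bcat-1 (3.73 ± 0.08), the last encoding a branched-chain amino acid aminotransferase. The probe sets of F53A9.6 and F53A9.8 are of kinds that can bind related transcripts, so their values may not be separate. The largest difference of an autosome from the other 4 was 0.05, for chromosome V. The X shift passed camera with the preset correlation of 0.01 (p = 1.6e-11) and with an estimated correlation (p = 0.013). The shift of single arrays was 0.46 ± 0.02 (SD, n = 3) in smo-1 RNAi and -0.00036 ± 0.06 (n = 3) in control embryos. Single arrays were set against the control mean, so the control value is small by construction. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows, with the control mean not recomputed for each permutation. The shift was small for dim genes: over 4 classes of rising level it was 0.02, 0.13, 0.50 and 0.46.

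The sdc-2(y93)+RNAi embryos gave an X effect for comparison. The smo-1 messenger was also 2.07-fold lower in them, so the values cannot be assigned to the sdc-2 allele alone. In sdc-2(y93)+RNAi embryos X-linked genes above the median level were higher relative to autosomal genes by 0.63, a 1.55-fold difference, and over genes of any level by 0.23. Above the median level the shift came with medians of 0.45 for X-linked and -0.18 for autosomal genes, and 92.6% of X-linked genes above the autosomal median. Of the X-linked genes, 36.6% rose and 2.04% fell, against 6.75% and 17.8% of autosomal genes (Fisher's exact test for the higher genes, odds ratio 7.99, p = 4.2e-300). C45B2.2 (4.54 ± 0.11), zig-3 (2.70 ± 0.10), F53A9.6 (2.47 ± 0.11, from a probe set that can bind related transcripts) and bcat-1 (2.24 ± 0.08) were the X-linked genes with the smallest adjusted p. The X shift passed camera with the preset correlation (p = 2.6e-37) and with an estimated one (p = 0.00056), and the shift of single arrays was 0.63 ± 0.07 (SD, n = 3; exact two-sided permutation p = 0.1 against control). Over the 4 level classes it was 0.03, 0.13, 0.54 and 0.71. Hybridisation controls, bacterial and phage transcripts added to the labelled material, stood far above background on the sdc-2(y93)+RNAi arrays alone. Of these, cre stood 7.54 over control arrays on the log2 scale, so the array batch and this group cannot be told apart. A batch has no chromosome, and the largest difference of an autosome from the others was 0.05, for chromosome IV. This argues against array handling as the cause of the X shift, but does not bear on another mix of embryo ages in that batch.

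Compared directly, the X shift of smo-1 RNAi embryos was smaller than that of sdc-2(y93)+RNAi embryos by a log2 difference of -0.16. The call rested on the setting: camera gave p = 0.043 with the preset correlation and p = 0.33 with an estimated one, and the exact two-sided permutation p of the shifts of single arrays was 0.1. Of the X-linked genes, 26.9% were lower in smo-1 RNAi than in sdc-2(y93)+RNAi embryos, against 15.7% of autosomal genes (Fisher's exact test, odds ratio 1.97, p = 9.7e-37). This p describes where the calls lie, since genes are not independent replicates. The shares of higher genes were alike, 18.9% of X-linked and 18.4% of autosomal genes. In the brightest of the 4 level classes the difference in X shift was -0.26. The comparison sets arrays without signal from the hybridisation controls against arrays with it.

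**Figure D2:**
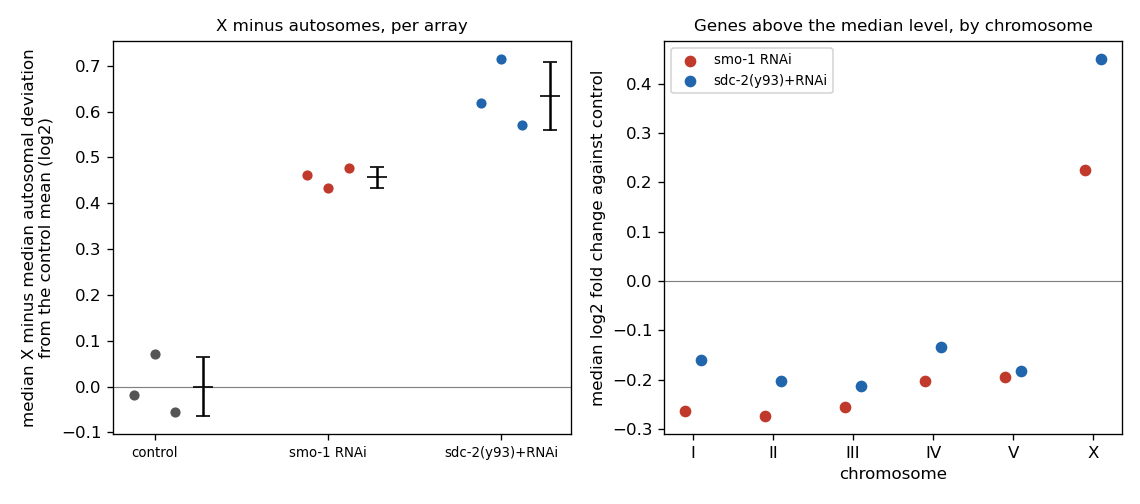
Left, the median deviation of X-linked genes from the control mean less that of autosomal genes (log2) on each array (points), with mean and SD per group of 3; right, the median log2 fold change against control by chromosome, for genes above the median level. The smo-1 RNAi arrays average 0.46 and the sdc-2(y93)+RNAi arrays 0.63, and X is the chromosome with positive medians, 0.23 and 0.45.

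With the deposited scaling, smo-1 RNAi changed more transcripts than sdc-2(y93)+RNAi, 6833 against 4535. The order turned with centring on autosomal genes above the median level, an alternative chosen after seeing the data, to 7459 against 8381. It held under the other alternatives tried, with 7557 against 4480 centred on autosomal genes. Over genes above the median level it was 5385 against 4446. The ratio of 3' to 5' probe sets, a sign of RNA integrity or labelling, differed from control for actin, GAPDH, ubiquitin and catalase by 0.66, -0.26, 0.32 and 0.86 on smo-1 RNAi arrays and by 0.81, 0.52, 0.34 and -0.08 on sdc-2(y93)+RNAi arrays (log2, n = 3 per group). The exact two-sided permutation p was 0.1 for each, but 0.6 for catalase on sdc-2(y93)+RNAi arrays, so differences in RNA quality stand beside the changes of genes and lists in both groups. Of 17118 genes, 3039 rose and 3794 fell in smo-1 RNAi embryos at a limma adjusted p of 0.05, 1175 and 730 of them by 2-fold or more. The highest were trf-2 (log2 6.63 ± 0.19), C45B2.2, grl-21 (5.92 ± 0.10), F14H12.3 (5.62 ± 0.14), nspe-7 (5.54 ± 0.22), the antimicrobial peptide gene nlp-29 (5.47 ± 0.18), dbd-13 (5.27 ± 0.19) and C53B7.3 (5.25 ± 0.23). The lowest were K01D12.1 (-3.88 ± 0.29), smo-1, H23N18.5 (-3.56 ± 0.20), C30E1.9 (-3.28 ± 0.19), F49D11.6 (-2.77 ± 0.23), T19H12.2 (-2.57 ± 0.26), C03C10.5 (-2.47 ± 0.12) and the cytochrome P450 gene cyp-35C1 (-2.38 ± 0.16). Probe sets of F14H12.3, nspe-7, nlp-29, C53B7.3, C03C10.5 and cyp-35C1 are of the kind that can bind related transcripts, so their values may be those of a family. In control embryos trf-2 lay at 5.27, no higher than the hybridisation control bioB, without signal there (5.41), so its change may be understated. The split depended on the scaling: 2390 genes rose and 5167 fell with each array centred on its autosomal genes, and 4967 and 2492 with centring on autosomal genes above the median level, which moved the median of all genes by 0.20.

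In smo-1 RNAi embryos 4 of 5 lists of tissue markers were higher, and early transcripts lower, than in control embryos. The exception, the largest tissue list, was that of epidermis and cuticle, with 30 of 157 genes higher and 21 lower, or 27 and 21 adjusted over the list alone (camera adjusted p = 0.147, 0.0288 to 0.342 over the alternatives tried). Its balance turned with the scaling, to 22 higher and 30 lower with centring on autosomal genes and 50 and 13 with centring on autosomal genes above the median level. The gene lists were fixed before the data were examined. Of 22 intestine genes 14 rose and 2 fell, or 14 and 3 adjusted over the list alone. Their median log2 fold change was 0.83 (camera adjusted p = 0.00031, but adjusted p = 0.39 with an estimated correlation). The protease genes cpr-1 (3.45 ± 0.10) and asp-6 (2.51 ± 0.14) and the intermediate filament gene ifb-2 (1.27 ± 0.10) were among them. Of 29 pharynx genes 14 rose and 5 fell, with the same counts adjusted over the list alone. The median was 0.39 (adjusted p = 0.008, but adjusted p = 0.59 with an estimated correlation), and abu-10 rose by 3.18 ± 0.23 and phat-8 by 2.27 ± 0.13. Of 34 neuronal genes 17 rose and 5 fell, or 18 and 6 adjusted over the list alone. Their median was 0.38 (adjusted p = 0.037, but adjusted p = 0.59 with an estimated correlation). They include the neuropeptide-processing genes egl-3 (2.08 ± 0.15) and egl-21 (1.77 ± 0.12). Of 25 body wall muscle genes 13 rose and 5 fell, or 13 and 6 adjusted over the list alone. Their median was 0.32 (adjusted p = 0.037, but adjusted p = 0.57 with an estimated correlation). The myosin gene unc-54 rose by 1.02 ± 0.09, and hlh-1, the gene of a muscle-specifying transcription factor, changed by -1.54 ± 0.14. With the members and the background placed on autosomes alone, an alternative chosen after seeing the data, the neuronal and muscle lists did not pass (adjusted p = 0.145 and 0.273). With centring on autosomal genes above the median level, also chosen after seeing the data, neither passed (0.135 each), and muscle did not pass with the mean of all probe sets (0.0803). Over genes above the median level the pharynx (0.103) and muscle (0.0536) lists did not pass. Centred on autosomal genes, then on those above the median level, 14 intestine genes rose and 4 fell, then 14 and 1, 14 and 6, then 18 and 3 for pharynx, 14 and 8, then 20 and 5 for neurons and 10 and 6, then 17 and 3 for muscle. Muscle passed under 1 of 5 alternatives and neurons under 3 of 5. Over all alternatives tried the adjusted p ranged from 0.000177 to 0.00103 for intestine, 0.00662 to 0.103 for pharynx, 0.0303 to 0.145 for neurons and 0.0471 to 0.273 for muscle.

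Of 19 early zygotic genes 0 rose and 11 fell in smo-1 RNAi embryos, or 0 and 12 adjusted over the list alone. Their median was -0.76 (camera adjusted p = 0.00053, but adjusted p = 0.39 with an estimated correlation). The epidermis-specifying factor gene elt-1 changed by -1.08 ± 0.09, sdz-28 by -1.32 ± 0.14 and vet-6 by -1.91 ± 0.21. Of 28 oocyte and early embryo maternal genes 5 rose and 16 fell, or 5 and 17 adjusted over the list alone. Their median was -0.37 (adjusted p = 0.011, but adjusted p = 0.59 with an estimated correlation). Among them puf-3 changed by -1.31 ± 0.16, cpg-1 by -1.09 ± 0.15 and oma-1 by -1.03 ± 0.15. The medians of the intestine, pharynx, neuronal, muscle, early zygotic and maternal lists kept their sign under each scaling tried. There were 0 early zygotic genes higher and 12 lower with centring on autosomal genes, then 0 and 10 with centring on those above the median level, and for maternal genes 2 and 20, then 6 and 11. Over all genes 14 lists passed, and over genes above the median level 5 did. The maternal list was among those lost (adjusted p = 0.177, the highest of 0.00275 to 0.177 over the alternatives tried), and the early zygotic list was not (0.000114 to 0.0058).

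Genes of the dosage compensation complex were lower in smo-1 RNAi embryos, though not past the threshold when only genes above the median level were tested. Of 10 genes 7 fell and 0 rose, with the same counts adjusted over the list alone. Their median was -0.42 (camera adjusted p = 0.02, but adjusted p = 0.47 with an estimated correlation). The condensin gene dpy-27 changed by -1.15 ± 0.08 and dpy-26 by -1.11 ± 0.11. Of 8 condensin genes, 4 of which are also in the dosage compensation list, 5 fell and 0 rose, or 6 and 0 adjusted over the list alone. Their median was -0.53 (adjusted p = 0.024, but adjusted p = 0.51 with an estimated correlation), and smc-4 changed by -0.89 ± 0.14. All members lay above the median level, where autosomal genes had a median of -0.24. Over genes above that level neither list passed (adjusted p = 0.15 for both, the highest of 0.00924 to 0.15 over the alternatives tried). With centring on autosomal genes above the median level, chosen after seeing the data, the medians were -0.22 and -0.33, with 4 genes lower in each list, and with centring on autosomal genes 7 and 6 were lower.

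A further 5 lists were lower over all genes, but 4 of these 5 were not past the threshold over genes above the median level. Of 27 DNA damage and cell death genes 14 fell and 1 rose, or 16 and 1 adjusted over the list alone. Of 36 histone genes 19 fell and 2 rose, or 22 and 2 adjusted over the list alone. Of 27 repressive chromatin genes 13 fell and 3 rose, or 14 and 3 adjusted over the list alone. Of 33 proteasome genes 12 fell and 2 rose, and of 13 Hox and Polycomb-related genes 6 fell and 0 rose, with the same counts adjusted over the list alone. In this order their medians were -0.34, -0.38, -0.37, -0.33 and -0.39, with camera adjusted p of 0.0032, 0.00053, 0.0042, 0.011 and 0.026. With an estimated correlation the adjusted p was 0.59, 0.49, 0.51, 0.74 and 0.39. Over genes above the median level it was 0.0988, 0.0309, 0.0988, 0.126 and 0.255 at the preset correlation, the highest of the alternatives tried, and the lowest were 0.000983, 0.000512, 0.000637, 0.00335 and 0.0127. With centring on autosomal genes above the median level the Hox and Polycomb-related list was also lost (0.0575), with 1 of 13 genes lower. The counts of lower and higher genes with that centring were 9 and 2 for DNA damage and cell death, 10 and 4 for histones, 10 and 3 for repressive chromatin and 9 and 4 for the proteasome, and with centring on autosomal genes 18 and 1, 26 and 2, 15 and 0, 19 and 1, and 8 and 0 for Hox and Polycomb-related genes. The medians kept their sign under each scaling tried. The DNA damage checkpoint kinase gene chk-1 changed by -1.23 ± 0.18 and the linker histone gene hil-2 by -1.42 ± 0.10. The histone deacetylase gene hda-1 changed by -1.33 ± 0.16 and the proteasome gene rpn-13 by -1.45 ± 0.20.

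Of 319 genes of the innate immune list 80 rose and 14 fell in smo-1 RNAi embryos, or 79 and 13 adjusted over the list alone. The list passed camera with adjusted p = 0.00031, but gave adjusted p = 0.39 with an estimated correlation. Its median was 0.06, and it turned to -0.08 with centring on autosomal genes, where 71 rose and 24 fell, and to -0.01 with quantile normalization; with centring on autosomal genes above the median level 120 rose and 8 fell. Besides nlp-29, fipr-21 (3.66 ± 0.11) and the lectin gene clec-41 (3.05 ± 0.09) were among the higher members. Germline genes went both ways, 11 higher and 7 lower of 30, with the same counts adjusted over the list alone (camera adjusted p = 0.10). The gene glh-1, of a Vasa-type RNA helicase of P granules, rose by 3.47 ± 0.18, the Argonaute gene csr-1 by 2.70 ± 0.19 and fbf-1 by 1.67 ± 0.08. The lists named next did not pass either. Of 20 sex determination genes 4 were higher and 4 lower, and of 20 heat shock genes 5 and 4, with the same counts adjusted over the list alone. Of 7 SUMO pathway genes 2 were higher and 2 lower, or 2 and 3 adjusted over the list alone. Of 24 oxidative and xenobiotic stress genes 4 were higher and 9 lower, or 4 and 10 adjusted over the list alone. Of 74 ribosomal protein genes 3 were higher and 6 lower, or 0 and 4 adjusted over the list alone, but 0 and 17 with centring on autosomal genes and 18 and 1 with centring on autosomal genes above the median level. Of 42 sperm genes 3 were higher and 0 lower, or 1 and 0 adjusted over the list alone. With the same centrings the counts were 1 and 3, then 12 and 0 for sperm, 10 and 7, then 12 and 3 for germline, 4 and 7, then 9 and 4 for heat shock, 1 and 3, then 3 and 2 for the SUMO pathway, 3 and 10, then 6 and 6 for oxidative stress and 3 and 6, then 7 and 4 for sex determination. Of the 42 sperm genes 1 lay above the median level, and of the 319 innate immune genes 67. Calls added there by the last centring can come from its constant of 0.20 alone. None of 5 yolk protein genes was called, also when adjusted over the list alone. Yolk transcripts, abundant in adult hermaphrodites, lay below the median level in all 5 cases, and vit-5 differed from control by 0.12 ± 0.10 (limma adjusted p = 0.36).

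**Figure D3:**
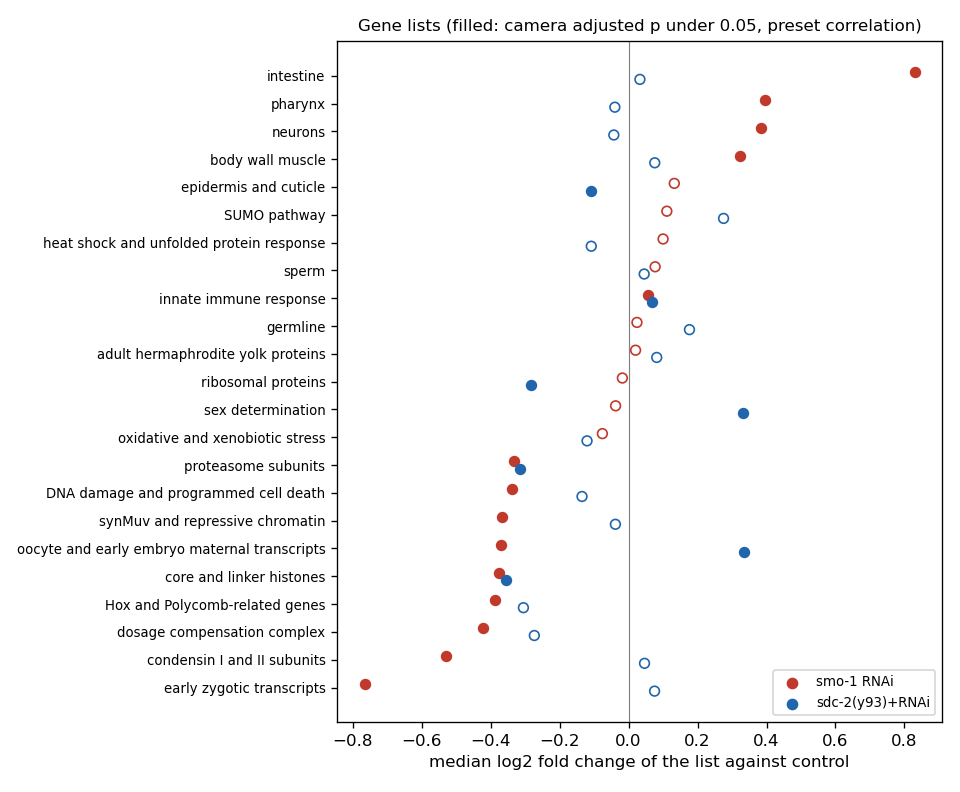
Median log2 fold change against control of each of the 23 gene lists (rows) in sdc-2(y93)+RNAi and smo-1 RNAi embryos, with filled points where camera gave an adjusted p under 0.05 at the preset correlation. Maternal transcripts lie at -0.37 in smo-1 RNAi and at 0.33 in sdc-2(y93)+RNAi embryos, and intestine genes at 0.83 and 0.03; no list keeps its call with an estimated correlation.

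In sdc-2(y93)+RNAi embryos 1860 genes rose and 2675 fell (limma adjusted p of 0.05), 345 and 349 of them by 2-fold or more. The highest were C45B2.2, dbd-13 (4.47 ± 0.19), the cystatin gene cpi-1 (4.28 ± 0.13), grl-21 (3.88 ± 0.10), tts-1 (3.30 ± 0.31), srlf-34 (3.24 ± 0.10), C53B7.3 (3.04 ± 0.23) and the antimicrobial peptide gene cnc-4 (3.03 ± 0.19). The lowest were H23N18.5 (-2.43 ± 0.20), T03D8.6 (-2.31 ± 0.14), the autophagy gene atg-9 (-2.17 ± 0.17), fmo-2 (-1.92 ± 0.17), mdt-29 (-1.87 ± 0.16), the alcohol dehydrogenase gene adh-1 (-1.86 ± 0.13), ncbp-2 (-1.85 ± 0.21) and anc-1 (-1.81 ± 0.18). With each array centred on its autosomal genes the split was 2260 higher and 2220 lower. With centring on autosomal genes above the median level, chosen after seeing the data, it was 6901 higher and 1480 lower, with the median of all genes moved by 0.26.

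Of 20 sex determination genes 10 rose and 1 fell in sdc-2(y93)+RNAi embryos, or 10 and 2 adjusted over the list alone. Their median was 0.33 (camera adjusted p = 8.8e-05, but adjusted p = 0.07 with an estimated correlation). Besides her-1, the sex switch gene xol-1 (1.96 ± 0.13) and the X signal element ceh-39 (1.33 ± 0.13) rose, though the other probe set of xol-1 gave 0.52 ± 0.08, and 5 of the 5 X-linked members were among the higher ones. Of the sex determination genes 15 rose and 0 fell with centring on autosomal genes above the median level. Of 28 maternal genes 10 rose and 0 fell, or 11 and 0 adjusted over the list alone, and 18 and 0 with that centring. Their median was 0.33 (adjusted p = 0.0004, but adjusted p = 0.73 with an estimated correlation), and mex-6 rose by 1.03 ± 0.13 and gld-1 by 0.86 ± 0.09. Of 74 ribosomal protein genes 37 fell and 0 rose, or 47 and 0 adjusted over the list alone (adjusted p = 8.8e-11, but adjusted p = 0.73 with an estimated correlation). Their median was -0.28, but -0.02 with 11 lower and 3 higher with centring on autosomal genes above the median level, and rps-27A changed by -0.82 ± 0.08. Of 36 histone genes 18 fell and 0 rose, or 21 and 0 adjusted over the list alone. Their median was -0.36 (adjusted p = 5.1e-06, but adjusted p = 0.72 with an estimated correlation), but -0.09 with 12 lower and 5 higher with that centring, and his-41 changed by -1.28 ± 0.12. Of 33 proteasome genes 13 fell and 2 rose, with the same counts adjusted over the list alone. Their median was -0.31 (adjusted p = 0.0025, but adjusted p = 0.77 with an estimated correlation), but -0.05 with 10 lower and 5 higher with that centring. The proteasome list did not pass over genes above the median level (adjusted p = 0.0524, the highest of 0.000348 to 0.0524 over the alternatives tried). Of 157 epidermis and cuticle genes 37 fell and 10 rose, or 38 and 10 adjusted over the list alone (adjusted p = 0.0044, but adjusted p = 0.77 with an estimated correlation). Their median was -0.11, and turned to 0.15, with 24 lower and 25 higher, with centring on autosomal genes above the median level. The cuticle collagen gene dpy-7 changed by -1.03 ± 0.10 and wrt-10 by -1.11 ± 0.11. Of 319 innate immune genes 28 rose and 14 fell, or 27 and 11 adjusted over the list alone (adjusted p = 0.0496, but adjusted p = 0.77 with an estimated correlation). With that centring 162 rose and 8 fell, and the median went from 0.07 to 0.33. It added a constant of 0.26 to each change, and 67 of the 319 genes lay above the median level. The added calls can therefore come from that constant alone.

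The remaining lists did not pass in sdc-2(y93)+RNAi embryos with the main settings. Under an alternative, germline, heat shock or oxidative stress genes did (lowest adjusted p 0.00637, 0.0444 and 0.0133, highest 0.217, 0.724 and 0.15). Among tissue markers, 7 genes were higher and 7 lower of 25 for body wall muscle, 7 and 1 of 22 for intestine, 4 and 6 of 34 for neurons and 3 and 7 of 29 for pharynx. Among germline and stage markers, 9 were higher and 3 lower of 30 germline genes, 4 and 1 of 19 early zygotic genes, 0 and 0 of 42 sperm genes and 0 and 0 of 5 yolk protein genes. The dosage compensation complex had 3 higher and 3 lower of 10, condensin 3 and 1 of 8 and the SUMO pathway 1 and 1 of 7. Of 20 heat shock genes 1 was higher and 6 lower, of 24 oxidative stress genes 1 and 9, and of 27 DNA damage and cell death genes 1 and 3. Of 13 Hox and Polycomb-related genes 3 were higher and 4 lower, and of 27 repressive chromatin genes 4 and 9. Adjusted over the list alone, no count of these lists moved by more than 3 genes, but the counts depended on the scaling. With centring on autosomal genes above the median level 21 sperm, 4 yolk protein and 8 early zygotic genes were higher and 0 lower in each, and 12 muscle genes were higher and 3 lower, 11 and 4 neuronal, 8 and 5 pharynx, 7 and 6 oxidative stress, 6 and 4 heat shock, 8 and 2 DNA damage and cell death and 11 and 6 repressive chromatin genes. The other lists then had 15 and 3 for germline, 5 and 1 for Hox and Polycomb-related genes, 10 and 1 for intestine, 5 and 1 for the SUMO pathway, 4 and 1 for condensin and 3 and 2 for the dosage compensation complex. This centring added 0.26 to every log2 change. Of 42 sperm genes 1 lay above the median level, and of 5 yolk protein genes 0. Their added calls can therefore come from that constant alone. The muscle genes hlh-1 and myo-3 changed by -1.12 ± 0.14 and -0.95 ± 0.13. Genes with several probe sets had them called in opposite directions in 171 of 1921 cases in sdc-2(y93)+RNAi and in 42 of 2120 cases in smo-1 RNAi embryos.

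Between the perturbations, 3154 genes were higher and 2947 lower in smo-1 RNAi than in sdc-2(y93)+RNAi embryos (limma adjusted p of 0.05); with centring on autosomal genes the split was 2236 and 6405. The highest were trf-2 (6.52 ± 0.19), F14H12.3 (4.84 ± 0.14), C40A11.8 (4.42 ± 0.13), spi-2 (4.12 ± 0.10), hpo-26 (3.96 ± 0.09) and srlf-35 (3.88 ± 0.08). The lowest were smo-1 (-2.62 ± 0.17), K01D12.1 (-2.61 ± 0.29), C30E1.9 (-2.49 ± 0.19), the cyclin D gene cyd-1 (-2.45 ± 0.17), zfp-3 (-2.31 ± 0.22) and F52D2.7 (-2.30 ± 0.10). The trf-2 level in sdc-2(y93)+RNAi embryos (5.38) lay near that of bacterial and yeast controls without signal (5.16), so its change may be understated. Of 28 maternal genes 20 were lower and 2 higher in smo-1 RNAi embryos (median -0.85, adjusted p = 6.3e-07), and of 19 early zygotic genes 10 were lower and 0 higher (-0.91, adjusted p = 5e-05). The counts were the same adjusted over the list alone, and both gave adjusted p = 0.29 with an estimated correlation. Of 29 pharynx genes 18 were higher and 4 lower (0.85, adjusted p = 6.3e-05), and of 22 intestine genes 13 and 3 (0.76, adjusted p = 0.00023), with the same counts adjusted over the list alone. With an estimated correlation these gave adjusted p = 0.45 and 0.29. Of 74 ribosomal protein genes 37 were higher and 1 lower, or 41 and 1 adjusted over the list alone (0.25, adjusted p = 4.5e-07, but adjusted p = 0.52 with an estimated correlation). The ribosomal split was 6 higher and 4 lower (median 0.05) with centring on autosomal genes. The medians of these 5 lists kept their sign under each scaling tried, and the counts of the other 4 stayed on the same side. A total of 13 lists passed camera at the preset correlation and none with an estimated one. Among the rest, 11 of 20 sex determination genes were lower and 2 higher (adjusted p = 0.0022, but 0.124 with autosomal members alone). The dosage compensation complex had 6 of 10 lower (0.0071, but 0.0722 over genes above the median level). Condensin had 5 of 8 lower (0.0025). Of 157 epidermis and cuticle genes 57 were higher and 15 lower (0.00035).

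Genes changed in both perturbations moved mostly together. There were 910 genes higher in both and 1758 lower in both, against 330 and 593 for independent lists. Another 171 and 241 moved in opposite directions. Of X-linked genes 478 were higher in both, against 300 for independent lists. These numbers for independent lists take no account of level, and calls were more frequent among brighter genes. Over the 8559 genes above the median level, 1994 rose in smo-1 RNAi and 1826 in sdc-2(y93)+RNAi embryos, 869 of them in both. There 3391 and 2620 fell, 1709 of them in both. Lists of like level were compared for higher autosomal genes alone. Across autosomal genes the covariance of the changes was 0.144, against 0.0087 from the shared control arrays alone, and across X-linked genes 0.199 against 0.0086; genes are not independent replicates. The correlation was 0.52 in both sets. Shared control arrays give 0.50 with no effect by construction, whatever the size of the noise, so the correlation does not show the size of a shared effect. With separate control arrays for the comparisons, in the 6 divisions of the 3 arrays, 176 to 303 autosomal genes were higher in both (429 with shared arrays), 2.52 to 3.74 times the number for independent lists of like level (limma, a lone array being taken to vary like the groups). The covariance across autosomal genes was then 0.116 to 0.160. As smo-1 was 2.07-fold lower in sdc-2(y93)+RNAi embryos too, and both groups had another feeding schedule than control, the overlap is not that of independent perturbations.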

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

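The tests of the array batch, of the shared control arrays, of lowered smo-1 and of the feeding schedule, and the check of the embryo-age test on made-up shifts, were chosen after the results were seen; the splits of the arrays and the embryo-age test itself were fixed before. Groups of 3 arrays are too small for a search for outlying samples. Signals outside the genes tested drew attention to the hybridisation controls, which the comparisons do not use: on sdc-2(y93)+RNAi arrays cre stood 7.54, bioD 5.48, bioC 3.14 and bioB 1.70 above control arrays on the log2 scale. Among 895 probe sets without a gene name here, 76 were higher and 74 lower in smo-1 RNAi than in control embryos. In sdc-2(y93)+RNAi embryos 45 were higher and 42 lower. They changed less often than all probe sets, 16.8% against 40.2% and 9.72% against 27.1%. Among 887 probe sets with several genes 161 were higher and 133 lower in smo-1 RNAi embryos, and 35 and 114 in sdc-2(y93)+RNAi embryos.

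The pattern on the sdc-2(y93)+RNAi arrays is that they alone carry signal from the hybridisation controls, so they may form a batch of their own. A batch of array handling has no chromosome, and the X shift of 0.63 lay far outside the shifts of the autosomes, of which the largest was 0.05. This argues against array handling as the cause of the X shift. It does not bear on another mix of embryo ages in that batch, which was not tested for this group. The batch is also not the whole cause of autosomal changes shared with smo-1 RNAi embryos, whose arrays lack the signal as control arrays do: with the trend with level removed, the covariance of the changes was 0.137 (95% range over resampled genes 0.125 to 0.149), against 0.0086 from the shared control arrays. For the 1465 autosomal genes called in sdc-2(y93)+RNAi embryos and not in the same direction in smo-1 RNAi embryos, batch and group cannot be told apart, since no other group has an array with the signal.

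The X shift of smo-1 RNAi embryos could come from lost dosage compensation or from a different mix of embryo ages. An age mix was considered since 4 of 5 lists of tissue markers were higher and early transcripts lower at the preset correlation. However, epidermis did not pass, muscle passed under 1 of 5 alternatives and none of these lists passed with an estimated correlation. With autosomal members alone the neuronal and muscle lists did not pass (camera adjusted p = 0.145 and 0.273). Their calls are therefore not independent of the X shift. The batch marked by signal from the hybridisation controls is not the cause, as these differed by at most 0.19 between smo-1 RNAi and control arrays. They were near background in both groups, so they cannot show whether those arrays were otherwise run together. The age test compared the X shift among genes matched on their sdc-2(y93)+RNAi change; it gave -0.23 (95% range -0.33 to -0.11), and the bound set beforehand, below 50% of 0.46, would count this against age, but the sign came from the 2 highest of 10 bins (-0.61 and -2.64, with 63 and 70 autosomal genes), the others lying at 0.03 to 0.15. That bound was wrong. Random autosomal genes were given a constant shift of 0.46 in smo-1 RNAi and of 0.63 in sdc-2(y93)+RNAi, the sizes of the X shifts. For these the same matching returned -0.12 (-0.18 to -0.06), so it loses such a shift. No shift of another kind was tried. Embryo age and lost dosage compensation therefore both stay open for the smo-1 RNAi shift. Every control mother also had another feeding schedule than the mothers of both other groups, so for neither X shift can schedule and perturbation be told apart.

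Autosomal genes higher under both perturbations numbered 429, 87 of them by 2-fold or more in both, among them dbd-13, cpi-1, grl-21, cnc-4 and nlp-29. Chance values of the shared control arrays are not the whole cause: with separate control arrays for the comparisons, in 6 divisions, 176 to 303 autosomal genes were higher in both, 2.52 to 3.74 times the number for independent lists of like level, and 173 to 281 of them were among the 429. The smo-1 messenger was also lower in sdc-2(y93)+RNAi embryos, by -1.05 and on each array, so lowered smo-1 may be the common cause; of the 429 genes 235 were higher in smo-1 RNAi than in sdc-2(y93)+RNAi embryos and 22 lower, as a smaller fall of smo-1 would give, but so would any weaker effect. The control mothers spent 96 hours on RNAi plates and the others 72 hours after 24 hours on HB101. No control array has the other schedule and no sdc-2(y93)+RNAi array has smo-1 at the control level, so for these 429 genes the feeding schedule, lowered smo-1 and another effect common to both perturbations cannot be told apart.

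For each of the 3 counts of changed genes, 1 of the 10 splits of the 6 arrays into 3 and 3 gave as many genes, the real one, and 10 splits are too few for a share under 0.05. The real counts were 6833, 4535 and 6101, and the highest count of another split was 0 in each comparison.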

How the results depend on the processing

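Centring on autosomal genes above the median level and lists of autosomal members were chosen after seeing the data. The X shifts of sdc-2(y93)+RNAi and smo-1 RNAi embryos kept their direction and their side of the threshold under every alternative run, with ranges of 0.58 to 0.67 and 0.44 to 0.49 when 1 array was left out. Their difference (-0.16; -0.19 to -0.12 leaving out 1 array) lost its camera call over all genes (-0.028), with the mean of all probe sets (-0.13), with quantile normalization on autosomal genes (-0.14), without smo-1 RNAi replicate 1 (-0.16) and without sdc-2(y93)+RNAi replicate 2 (-0.12); the cause was not tested. Counts of changed genes ranged from 5678 to 6263, 3555 to 4461 and 5243 to 6799 when 1 array was left out; a minimum fold of 1.5 left 4301, 2573 and 3778 genes and an adjusted p of 0.01 left 2986 in sdc-2(y93)+RNAi embryos, by construction, and centring on autosomal genes above the median level gave 8381 there. Genes shared by both perturbations numbered 552 higher and 1077 lower at an adjusted p of 0.01, by construction. The odds ratio of X-linked genes among those higher in smo-1 RNAi than in sdc-2(y93)+RNAi embryos, 1.04 (Fisher's exact test, p = 0.53), was 0.88 among genes above the median level (p = 0.071). Lists past the threshold fell from 14 to 5 in smo-1 RNAi embryos when only genes above the median level were tested; the cause was not tested. With autosomal members alone, the muscle and neuronal lists lost their calls in smo-1 RNAi embryos and the epidermis and germline lists gained one (adjusted p = 0.0288 and 0.0395), and in sdc-2(y93)+RNAi embryos the germline and oxidative stress lists gained one (0.00637 and 0.0459). There the germline and heat shock lists also gained one with the mean of all probe sets (0.0395 and 0.0444), and oxidative stress with centring on autosomal genes above the median level (0.0133). The replicate numbers showed no clear pairing of the arrays: deviations of arrays with the same number correlated at -0.22 to 0.24, and 5 of 9 arrays correlated best with one of their own number. With 3 arrays per group this check cannot exclude a pairing. With the replicate block 6829, 4549 and 6084 genes changed, the X shifts stayed at 0.46, 0.63 and -0.16, and 14, 7 and 13 lists passed. Of the settings tried on named genes 1749 left the call as it was, 26 ended it and 5 made one; her-1 in smo-1 RNAi embryos (0.32) lost its call with the block, with trend and robust settings and without control replicate 2 or 3 or smo-1 RNAi replicate 2 or 3. No named gene that was called reversed, nor did the camera direction of a called list, but medians of called lists changed sign: epidermis in sdc-2(y93)+RNAi embryos (-0.11) was 0.15 with centring on autosomal genes above the median level, and innate immune in smo-1 RNAi embryos (0.06) was -0.08 with centring on autosomal genes and -0.01 with quantile normalization. In the direct comparison innate immune (0.03) was -0.03, -0.17 and -0.0074 with these scalings and neurons (0.18) was -0.014 with centring on autosomal genes; the cause was not tested. Dim signal limits the genes below the median level, where the X shift is small.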

Other observations

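The X shift was present along the whole X chromosome. With the X-linked genes above the median level ordered by position and divided into 5 parts of 276 genes, it was 0.35, 0.54, 0.62, 0.40 and 0.40 in smo-1 RNAi embryos and 0.60, 0.65, 0.69, 0.65 and 0.57 in sdc-2(y93)+RNAi embryos; differences between the parts were not tested.

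Stress genes of smo-1 RNAi embryos went in both directions. Of 24 oxidative and xenobiotic stress genes 4 rose and 9 fell, and of 20 heat shock genes 5 and 4. The small heat shock genes hsp-17 (2.51 ± 0.18) and hsp-43 (2.19 ± 0.12), the metallothionein gene mtl-1 (2.65 ± 0.22) and the glutathione transferase gene gst-5 (2.39 ± 0.23) rose (limma). The genes dnj-27 (-1.88 ± 0.16) and cyp-35C1 (-2.38 ± 0.16) fell. In sdc-2(y93)+RNAi embryos the catalase gene ctl-2 (-1.47 ± 0.11), gst-10 (-1.37 ± 0.15) and the chaperone gene hsp-1 (-0.97 ± 0.11) fell. Cuticle collagen genes col-163 (3.10 ± 0.12) and col-103 (3.15 ± 0.19) rose in smo-1 RNAi embryos, while noah-2 (-1.49 ± 0.09) fell. In control embryos mtl-1 (5.14) and col-163 (4.99) lay near the level of bacterial and yeast controls without signal (5.13), so their changes may be understated.

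The smo-1 messenger was lower in sdc-2(y93)+RNAi than in control embryos by a log2 change of -1.05 ± 0.17 (limma). All 3 arrays lay below all 3 control arrays. It was read by 1 probe set, with a mean level of 10.88 there, 8.26 in smo-1 RNAi and 11.93 in control embryos. The growth protocol covers both smo-1 RNAi and sdc-2 RNAi but names smo-1 alone as the target of the double-stranded RNA. It does not settle which double-stranded RNA the sdc-2(y93) mothers received.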
